A study of Mus musculus with 12 samples.

How the data were processed

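Whole-transcript expression arrays of the injured spinal cord of mice were analysed, 12 in all, with 4 each from wild-type mice, mice lacking Il1a and mice lacking Il1b. The deposited log2 values, made by the authors from the array scans, were used as they stand, with 1 value per probe set and array. Per the submitters' processing notes GCOS 1.4, RMA, limma and Partek were used, with no role or order given for any of them. That the values are RMA summaries on the log2 scale was inferred from this list and from the values, which ran from 2.97 to 14.4 with near-equal quantiles in every array. RMA corrects background, gives all arrays the same distribution and summarises the probes of a set, so an overall shift in RNA amount between groups would not show, and fold changes of dim genes are compressed. No detection calls were used. The scans were not analysed here, and the genome build of the platform's annotation was not given in the sources used here. Of 35557 probe sets, 477 held the same values as another probe set, and every value column matched a sample.

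The platform's annotation listed 23410 of the probe sets. Of these, 21789 had exactly 1 gene symbol and were used, and 1621 with several symbols were left out, as were 12147 probe sets without a listed gene. Where a gene had more than 1 probe set (999 genes), the set with the highest mean over all arrays stood for it, which left 19938 genes. The order of genes along the chromosomes was taken from RefSeq genes of GRCm38.p6, matched by Entrez gene identifier, which placed 19856 genes. Matched genes were given their RefSeq symbols. Il1r1, the signalling receptor of both cytokines, was among the genes to be named but had no probe set with 1 symbol and was not analysed here.

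Groups were compared with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 12 arrays, and the 3 contrasts (each knockout against wild type, and the Il1a KO against the Il1b KO) were tested with moderated statistics without a trend, two-sided. Adjusted p is the Benjamini-Hochberg value over all genes within a contrast, with 0.05 as the threshold. The sign of a log2 fold change is that of the knockout minus wild type, or of the Il1a KO minus the Il1b KO. No totals of counts exist for arrays, and their number limits the precision. The labels call the arrays biological replicates but name no animals, so a p measures the spread between these arrays. In simulated data with the spread of these arrays and independent genes, changes of 0.5 on the log2 scale were recovered in 91.0% of genes for the Il1a KO, 93.4% for the Il1b KO and 91.8% between the knockouts. Changes of 0.25 were recovered in 50.6%, 51.0% and 47.8%, and 5.25%, 5.22% and 5.88% of calls were false. Each simulation changed 200 genes, by 0.25, 0.5 or 1, more than were called in the real contrasts (34, 162 and 130). Recovery at an adjusted p depends on how many genes change, so it may be lower in the real data, above all in the Il1a KO.

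Gene lists were tested with camera, limma's competitive set test, at a preset correlation of 0.01 between members, with adjustment over the 23 lists that had at least 5 measured members and were of cell types or pathways. Tested on 20 simulated data sets, camera called a list of 25 independent genes shifted by 0.15 in 100% of them, which does not test lists whose members vary together. The cell type lists were markers of neurons, motor neurons, astrocytes, mature oligodendrocytes, oligodendrocyte precursors, homeostatic microglia, infiltrating monocytes and macrophages, neutrophils, lymphocytes and natural killer cells, endothelium, pericytes and fibroblasts, Schwann cells and dorsal root, and skeletal muscle. The pathway lists were the interleukin-1 family, NF-kB feedback and acute-phase targets, cytokines and chemokines, interferon-stimulated genes, reactive astrocyte genes, cell death regulators, cell cycle genes, endoplasmic reticulum stress genes, immediate early and heat shock genes, and cholesterol synthesis genes. Erythroid, mitochondrially encoded, ribosomal protein and sex-linked genes were summarised without a set test. Il1a and Il1b were left out of the list tests. Camera with a correlation estimated in each list and fry, which tests whether the genes of a list move on balance in 1 direction, were the alternatives.

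Named genes followed a rule. For each contrast these were the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold. Il1a, Il1b, Il1rn and Tox3 were always named, as were the 3 members with the smallest p of each list that passed and of the neutrophil, cytokine, mature oligodendrocyte and cell death lists. Genes named outside this rule, such as neighbours of a locus and members of lists that did not pass, were chosen after their values were seen. The rule, the lists, the tests and the first set of alternatives were chosen before the data were examined.

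The overlap of the knockouts was set beside unchanged groups simulated against the same wild-type arrays and beside fits in which the wild-type arrays were split between the comparisons. Genes within 100 measured neighbours of Il1a were compared with all other placed genes by Fisher's exact test, two-sided, adjusted over the 3 contrasts. Alternatives covered the fit, the normalization, the choice of probe sets and genes, the thresholds, the size of the window, the replicate number as a block and the omission of each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.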

Results

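Gene expression was measured in the injured spinal cord of wild-type C57BL/6 mice and of mice lacking interleukin-1 alpha (Il1a KO) or interleukin-1 beta (Il1b KO), the 2 main agonists of the interleukin-1 receptor. The cord was contused with a force of 50 kdyn, and a 6 mm segment centred on the lesion was taken 24 h later from mice aged 8 to 12 weeks. Each of the 3 groups was represented by 4 arrays, which the labels call biological replicates, so 12 arrays were compared. The array medians lay between 7.67 and 7.72 on the log2 scale, and any pair of arrays correlated across genes with r between 0.988 and 0.997. The first principal component carried 33.0% of the variance between arrays and separated wild type replicate 1 (score 20.2) from Il1b KO replicate 3 (score -13.6) and wild type replicate 3 (score -10.2), but not the genotypes. The second (15.3%) separated wild type (0.93 to 13.8) from the Il1b KO (-7.96 to -3.29), with the Il1a KO at -4.01 to 1.69. The third (12.4%) separated the Il1a KO (3.35 to 12.9) from all other arrays (at most 0.61). Il1a KO replicate 1 differed from every other array in sex-linked genes. Its Xist value was 6.47 against 11.9 to 12.2 in the other arrays. Its value for the Y-linked gene Eif2s3y was 9.15 against 3.65 to 3.94. This is the profile of a male among females, so sex was not balanced between the groups, though the labels give no sex.

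The targeted genes were examined before any other. Il1b averaged 7.83 ± 0.161 (SD, n = 4) in wild type and 6.42 ± 0.183 (SD, n = 4) in the Il1b KO, and its highest Il1b KO array (6.63) lay below its lowest wild-type array (7.68). This was a 2.67-fold lower level, with a log2 fold change of -1.42 (SE 0.0939, limma adjusted p = 2.64e-06). Il1a averaged 5.87 ± 0.232 (SD, n = 4) in wild type and 4.97 ± 0.0749 (SD, n = 4) in the Il1a KO, 1.87-fold lower (log2 fold change -0.90, SE 0.113, limma adjusted p = 0.00372). Il1a was also lower in the Il1b KO, at 5.10 ± 0.209 (SD, n = 4), 1.71-fold below wild type (log2 fold change -0.77, limma adjusted p = 0.0039), and the difference between the knockouts did not pass the test (log2 difference -0.13, adjusted p = 0.849). Il1b in the Il1a KO was 8.08 ± 0.0946 (SD, n = 4), a log2 difference of 0.25 from wild type that did not pass the test (adjusted p = 0.465). Il1a lay at percentile 9.37 of all genes by mean level, so its fold changes are compressed towards the array background. The deleted exons and the positions of the probes were not given in the sources used here, so signal left in a knockout does not show remaining transcript. Il1rn, the natural antagonist of the receptor, did not pass the test in either knockout (log2 fold change 0.09, adjusted p = 0.929, in the Il1a KO and 0.38, adjusted p = 0.198, in the Il1b KO).

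**Figure D1:**
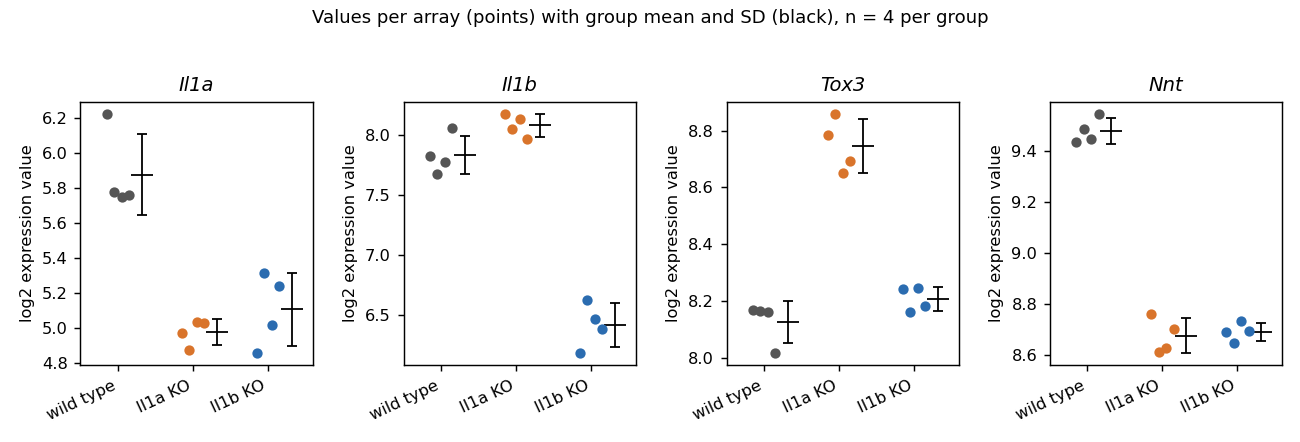
Log2 expression values of Il1a, Il1b, Tox3 and Nnt on the vertical axes, with each array as a point and the group mean and SD (n = 4) in black beside the points. Il1b was low in the Il1b KO alone (mean 6.42), Il1a was below wild type in both knockouts, Tox3 was high in the Il1a KO alone (mean 8.75), and Nnt was below wild type in both knockouts (means 8.68 and 8.69 against 9.48).

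The comparison of the Il1a KO with wild type asked which transcripts of the lesioned cord differ in mice that lack interleukin-1 alpha. Lrmda and Entpd4, a nucleotide-hydrolysing enzyme of the Golgi, had the largest rises, at 1.85-fold (log2 fold change 0.88, SE 0.0511, adjusted p = 1.61e-06) and 1.64-fold (log2 fold change 0.72, SE 0.0325, adjusted p = 2.26e-07). Apart from Il1a, the largest falls were those of Gabra2, a subunit of the inhibitory GABA-A receptor, at 1.81-fold lower (log2 fold change -0.86, SE 0.0602, adjusted p = 1.37e-05), and of Nnt, the mitochondrial transhydrogenase that supplies NADPH, at 1.74-fold lower (log2 fold change -0.80, SE 0.0431, adjusted p = 9.82e-07). Lrmda, Gabra2 and Nnt also passed in the Il1b KO (log2 fold changes 0.81, -0.69 and -0.79), so their changes were not particular to the Il1a KO. Tox3, a nuclear protein with an HMG box, rose 1.54-fold, from 8.13 ± 0.0740 (SD, n = 4) to 8.75 ± 0.0941 (SD, n = 4) (log2 fold change 0.62, SE 0.0526, limma adjusted p = 1.08e-04). Tox3 was named in advance because the published study singled it out on these same samples, so its call here is not independent evidence. In all, 34 of 19938 genes passed, of which 15 were higher and 19 lower, and 10 of them changed by at least 1.5-fold. The arrays of the groups did not overlap in 5.06% of all genes, against the 2.86% that chance gives.

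Among the other genes that rose in the Il1a KO were Pkd2l1, a channel of neurons that contact the cerebrospinal fluid (1.61-fold), and Ankub1 (1.54-fold). Aim2, a sensor of cytosolic DNA that assembles an inflammasome, rose 1.43-fold, and further rises were those of Hsd11b1, which regenerates active glucocorticoid (1.37-fold), and of Coq9, needed for ubiquinone synthesis (1.34-fold). Aqp6 (1.26-fold), Olfml1 (1.26-fold), Egfem1 (1.23-fold) and the sodium channel subunit Scn4b (1.22-fold) completed the 12 largest rises. Falls were found for Sprr1a, a protein induced in regenerating axons (1.62-fold lower), Cd59a, an inhibitor of the complement membrane attack complex (1.52-fold lower), the long noncoding RNA Crnde (log2 fold change -0.58), the chemokine Ccl28 (1.46-fold lower) and Wdfy1 (1.43-fold lower). Znrd1as (log2 fold change -0.48), Acat3 (1.36-fold lower), Gadd45gip1 (1.35-fold lower) and Mri1, an enzyme of methionine salvage (1.31-fold lower), followed. Each of these genes had no overlap between the 4 arrays of the Il1a KO and the 4 of wild type, and their adjusted p ranged from 2.89e-04 for Crnde to 0.0388 for Olfml1. Besides Tox3 itself, 5 of the 34 genes (Coq9, Crnde, Gadd45gip1, Mri1 and Wdr83os) lay within 100 measured neighbours of Tox3 on chromosome 8. Ccl28 lay with Nnt in a stretch of 6 measured genes on chromosome 13. Leaving out wild type replicate 4, Il1a KO replicate 3 or Il1a KO replicate 4 lowered the count to 18, 19 and 19 genes, and leaving out Il1a KO replicate 1, the array with the other sex-linked profile, lowered it to 23. Of 23 named genes other than Il1a, 8 lost their call in at least 1 such fit (Acat3, Aim2, Coq9, Egfem1, Olfml1, Pkd2l1, Scn4b and Znrd1as, with adjusted p up to 0.173 for Olfml1 without Il1a KO replicate 1).

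Cell type and pathway lists were compared as groups in the Il1a KO with camera, at a preset correlation between members. Markers of mature oligodendrocytes were higher as a group, with 26 of 28 members at a positive log2 fold change, a mean of 0.13 and an adjusted p of 1.31e-11, and the call was lost with an estimated correlation (adjusted p = 0.261 with an estimated correlation). Opalin had a log2 fold change of 0.53 (adjusted p = 0.16), Gpr37 of 0.30 (adjusted p = 0.129) and Tspan2 of 0.26 (adjusted p = 0.239). Of the members 0 passed over all genes and 7 passed when adjusted over the list alone. Oligodendrocyte precursor markers were also higher as a group (mean 0.08, adjusted p = 1.82e-04, and adjusted p = 0.261 with an estimated correlation), with C1ql1 at 0.19 and Olig1 at 0.20 but Bmp4 at -0.20. For this list 0 members passed over all genes, against 6 higher and 1 lower adjusted over the list alone. Cholesterol synthesis genes had a positive log2 fold change in 17 of 17 members (mean 0.07, adjusted p = 6.57e-04, and 0.551 with an estimated correlation), among them Stard4 at 0.12, Mvk at 0.10 and Hsd17b7 at 0.10. Markers of neurons were higher as well (mean 0.04, adjusted p = 0.0187, and 0.584 with an estimated correlation), with Rbfox3 at 0.12, Scn1a at 0.17 and Gad1 at -0.10. So were markers of astrocytes (mean 0.05, adjusted p = 0.0368, and 0.596 with an estimated correlation), with Gja1 at 0.15, Slc6a11 at 0.16 and Ntsr2 at 0.14. In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The cholesterol call was lost without wild type replicate 1 (mean 0.04, adjusted p = 0.259), and without Il1a KO replicate 1 the mean was 0.04 (adjusted p = 0.047). The neuron call was lost without wild type replicate 1 (mean 0.04, adjusted p = 0.0793), wild type replicate 4 (0.03, adjusted p = 0.0828) or Il1a KO replicate 1 (0.02, adjusted p = 0.138). The astrocyte call was lost without wild type replicate 1 (0.06, adjusted p = 0.06), replicate 3 (0.03, adjusted p = 0.236) or replicate 4 (0.03, adjusted p = 0.162), or Il1a KO replicate 1 (0.04, adjusted p = 0.0745). Il1a KO replicate 1, the array with the other sex-linked profile, was the highest of its group in mature oligodendrocyte markers (list mean 11.48 against 11.36 to 11.40) and precursor markers (9.19 against 9.08 to 9.11).

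By camera at the preset correlation 8 lists were lower as groups in the Il1a KO. Genes of reactive astrocytes had a negative log2 fold change in 27 of 29 members (mean -0.14, adjusted p = 5.80e-11, and 0.261 with an estimated correlation), and Timp1 was at -0.43, S100a10 at -0.22 and Gfap, the intermediate filament of astrocytes, at -0.12. Of these members 0 passed over all genes and 11 were lower when adjusted over the list alone. Neutrophil markers were lower in 21 of 25 members (mean -0.16, adjusted p = 6.57e-04, and 0.584 with an estimated correlation), with Ly6g at -0.45 (SE 0.0905, adjusted p = 0.098), Mmp9 at -0.35 and Csf3r at -0.36, and 1 member passed adjusted over the list alone. NF-kB feedback and acute-phase targets (mean -0.11, adjusted p = 5.22e-04, and 0.261 with an estimated correlation) included the acute-phase genes Saa2 at -0.39, Saa1 at -0.35 and Hp at -0.32, and 0 members passed either way. Regulators of cell death (mean -0.05, adjusted p = 0.00141, and 0.261 with an estimated correlation) included Mlkl, the effector of necroptosis, at -0.26 (adjusted p = 0.108), Gadd45a at -0.22 and Casp6 at -0.12, with 2 members lower adjusted over the list alone. Monocyte and macrophage markers were lower (mean -0.08, adjusted p = 0.0201, and 0.603 with an estimated correlation), with F13a1 at -0.30, Fn1 at -0.19 and Chil3 at -0.82. The interleukin-1 family was lower (mean -0.08, adjusted p = 0.0436, and 0.584 with an estimated correlation), with Il1r2, the decoy receptor, at -0.67, Irak2 at 0.15 and Il33 at -0.18. Endoplasmic reticulum stress genes were lower (mean -0.04, adjusted p = 0.0393, and 0.386 with an estimated correlation), with Nupr1 at -0.29, Dnajc3 at -0.11 and Trib3 at 0.09. Each of these 3 lists had 0 members past the test over all genes and 1 adjusted over the list alone. Skeletal muscle genes, a sign of muscle carried over at dissection, were lower in 14 of 14 members (mean -0.16, adjusted p = 1.06e-05, and 0.272 with an estimated correlation), with Acta1 at -0.31, Tnnc2 at -0.15 and Myh1 at -0.14 and 0 members past the test either way. The muscle list mean varied more between wild-type arrays (SD 0.163) than between Il1a KO arrays (SD 0.0249), and its exact permutation p was 0.143. Cytokines and chemokines did not pass as a group (mean -0.0046, adjusted p = 0.435), with Ccl5 at -0.31, Ccl12 at 0.27 and Ccl6 at -0.23, 0 members past the test over all genes and 1 lower adjusted over the list alone. The immediate early and heat shock list did not pass (mean -0.05, adjusted p = 0.0695). Its member Atf3, a stress-induced transcription factor named here after its value was seen, fell 1.29-fold (adjusted p = 0.0272). Over the 13 lists that passed, 0 of 285 members passed over all genes by limma, and 75 had an unadjusted p under 0.05. With an estimated correlation 0 of the 13 calls held (3 lists at an unadjusted p under 0.05), and with fry 0 held (5 lists at an unadjusted p under 0.05). Without wild type replicate 4 the number of lists was 7. Il1a KO replicate 1 was the lowest of its group in reactive astrocyte genes (list mean 10.02 against 10.19 to 10.21) and NF-kB targets (8.04 against 8.18 to 8.21), and without it the NF-kB mean was -0.07 (adjusted p = 0.00788). The neutrophil call was lost without wild type replicate 4 (mean -0.11, adjusted p = 0.0516). The monocyte and macrophage call was lost without wild type replicate 3 (-0.04, adjusted p = 0.362), wild type replicate 4 (-0.05, adjusted p = 0.162) or Il1a KO replicate 1 (-0.04, adjusted p = 0.168), while without wild type replicate 1 the mean was -0.13 (adjusted p = 4.50e-04). The interleukin-1 family call was lost without wild type replicate 3 (-0.06, adjusted p = 0.362), wild type replicate 4 (-0.06, adjusted p = 0.162), Il1a KO replicate 1 (-0.06, adjusted p = 0.138) or Il1a KO replicate 2 (-0.08, adjusted p = 0.0589). The endoplasmic reticulum stress call was lost without wild type replicate 2 (-0.03, adjusted p = 0.14), replicate 3 (-0.03, adjusted p = 0.255) or replicate 4 (-0.04, adjusted p = 0.0516), or Il1a KO replicate 3 (-0.03, adjusted p = 0.141).

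**Figure D2:**
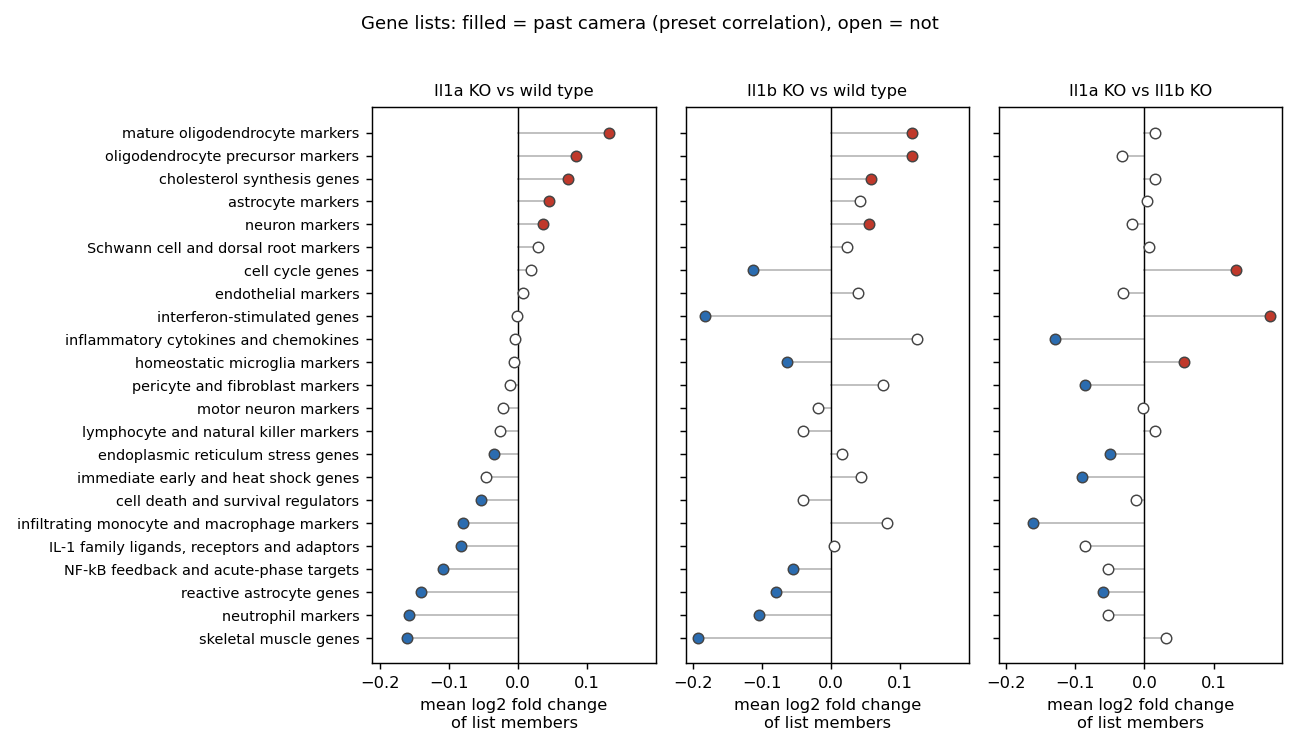
Mean log2 fold change of the members of each of 23 gene lists on the horizontal axis, with a panel for each comparison. Filled points passed camera at a preset correlation (13, 11 and 9 lists) and open points did not, and with an estimated correlation 0 lists passed in each panel.

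The comparison of the Il1b KO with wild type asked the same question for interleukin-1 beta. Gdpd3, a glycerophosphodiesterase that forms lysophosphatidic acid, rose 8.01-fold, from 6.50 ± 0.158 (SD, n = 4) to 9.50 ± 0.221 (SD, n = 4) (95% interval of the log2 fold change 2.79 to 3.21, SE 0.0976, limma adjusted p = 3.3e-09). Pla2g4e, a cytosolic phospholipase, rose 2.91-fold (log2 fold change 1.54, SE 0.0676, adjusted p = 4.43e-08), and Cxcl13, a chemokine that attracts B cells, rose 2.37-fold (log2 fold change 1.25, SE 0.151, adjusted p = 7.67e-04). The complement inhibitor Cd59a fell 3.33-fold (log2 fold change -1.73, SE 0.0735, adjusted p = 4.43e-08), and the related genes Trim30d and Trim12a fell 3.41-fold and 3.21-fold. In all, 162 of 19938 genes passed, 84 higher and 78 lower, and 32 of them changed by at least 1.5-fold, 11 higher and 21 lower. Which direction held more genes depended on the processing, as 68 were higher and 84 lower when the values were quantile-normalized again. The arrays of the groups did not overlap in 7.00% of all genes, against the 2.86% that chance gives.

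Further rises in the Il1b KO were those of Il1bos, a transcript antisense to Il1b (1.93-fold), Masp2, a protease of the lectin pathway of complement (1.91-fold), Lrmda (1.76-fold), Fam169a (1.65-fold), the mitochondrial ribosomal protein gene Mrpl20 (1.63-fold), Elovl7, an elongase of fatty acids (1.61-fold), Rbm46 (1.55-fold), Depdc7 (1.51-fold) and Cxcl11, an interferon-inducible chemokine (1.48-fold). G530011O06Rik had the largest fall (4.41-fold lower, log2 fold change -2.14, SE 0.228). AA467197 fell 2.77-fold, the lipoxygenase Alox8 2.38-fold, Ly86, a partner of a Toll-like receptor homologue on B cells and macrophages, 2.10-fold, and the ribosomal protein gene Rpl34 2.07-fold. Arntl2, a transcription factor of the clock family, fell 1.86-fold, the peptide gene Uts2 1.78-fold and the protease inhibitor Spint1 1.74-fold. The arrays of the Il1b KO and of wild type did not overlap in any of these genes, and their adjusted p ranged from 4.43e-08 to 0.0154. Tox3 did not pass the test in the Il1b KO (log2 fold change 0.08, SE 0.0526, adjusted p = 0.559). AA467197, Il1bos and Il1b lay within 100 measured neighbours of Il1a, and Cxcl13 and Cxcl11 lay with Naaa and Shroom3 in a stretch of 19 measured genes on chromosome 5. Further genes above lay in runs of genes past the test with gaps of at most 10 measured neighbours. These were Cd59a and Depdc7 with Cd59b, Pla2g4e with Tyro3, Zfp106 and Snap23, and Trim12a with Trim30d. Ly86 lay with Ssr1, Rpl34 with Etnppl, Fam169a with F2r and Rbm46 with Gucy1a1. Mrpl20 lay with Mxra8, Acap3, C1qtnf12 and Gm16008, and Spint1 with Srp14, Ivd, Rmdn3 and Rhov. The runs of Spint1 and Pla2g4e lay on chromosome 2, the chromosome of Il1a and Il1b. They came directly before the run of Lcmt2, which had an offset of -98 measured genes from Il1a. Within 200 measured neighbours of Il1a 22 genes passed, against 13 within 100. Arntl2 lay with Abcc9, Bcat1, Etfrf1 and Med21. Leaving out wild type replicate 4 or Il1b KO replicate 1 lowered the count to 106 and 107 genes. Of the 27 named genes that passed here, other than the targeted genes, Itgam alone lost its call in such a fit.

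Oligodendrocyte lists were higher as groups in the Il1b KO as well, by camera at the preset correlation. Mature oligodendrocyte markers had a positive log2 fold change in 25 of 28 members (mean 0.12, adjusted p = 6.37e-07, and 0.39 with an estimated correlation), and Enpp6, an enzyme of newly forming oligodendrocytes, was at 0.40 (SE 0.0900, adjusted p = 0.0648), Gpr37 at 0.26 and Klk6 at 0.14. Precursor markers were higher in 17 of 19 members (mean 0.12, adjusted p = 4.28e-05, and 0.39 with an estimated correlation), with Gpr17 at 0.48, C1ql1 at 0.25 and Tnr at 0.22. In these lists 0 members passed over all genes, and 4 and 3 were higher adjusted over the list alone. Neuron markers were higher (mean 0.05, adjusted p = 0.00372, and 0.586 with an estimated correlation), with Slc12a5 at 0.18, Kcnc1 at 0.15 and Rbfox3 at 0.12. Of these, 3 members were higher adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes were higher (mean 0.06, adjusted p = 0.0384, and 0.672 with an estimated correlation), with Mvd at 0.17, Mvk at 0.11, Srebf2 at 0.09 and 0 members past the test either way. The cholesterol call was lost without wild type replicate 1 (mean 0.02, adjusted p = 0.831) or Il1b KO replicate 1 (0.05, adjusted p = 0.0866), replicate 3 (0.04, adjusted p = 0.22) or replicate 4 (0.05, adjusted p = 0.114), while without Il1b KO replicate 2 the mean was 0.09 (adjusted p = 0.0018).

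Neutrophil markers were lower as a group in the Il1b KO (17 of 25 members, mean -0.10, adjusted p = 0.00212, and 0.595 with an estimated correlation). Within the list Ly6g, a surface marker of mouse neutrophils, fell 1.47-fold (log2 fold change -0.55, SE 0.0905, adjusted p = 0.00869) and Itgam, the integrin alpha M chain of myeloid cells, fell 1.39-fold (log2 fold change -0.48, SE 0.0966, adjusted p = 0.0384) and lay near Rusf1, a gene past the test on chromosome 7 that was named after its value was seen, while Mmp9 was at -0.29 (adjusted p = 0.258). These 2 passed both over all genes and adjusted over the list alone. The neutrophil list averaged 7.06 in Il1b KO replicate 1 against 7.36 to 7.57 in the other 3 arrays, and without that array the mean difference was -0.0053 and the call was lost (adjusted p = 0.175). Without wild type replicate 4 the mean was -0.06 (adjusted p = 0.0319), and without Il1b KO replicate 2 it was -0.18 (adjusted p = 4.59e-05). Cell cycle genes were lower in 21 of 24 members (mean -0.11, adjusted p = 9.20e-06, and 0.39 with an estimated correlation), with Bub1b at -0.52, Plk1 at -0.23 and Mcm6 at -0.15, 0 members past the test over all genes and 1 adjusted over the list alone. Interferon-stimulated genes were lower in 22 of 24 members (mean -0.18, adjusted p = 7.34e-05, and 0.595 with an estimated correlation), with Oasl2 at -0.60, Gbp3 at -0.38 and Ifit2 at -0.24, and again 0 and 1 members passed. Homeostatic microglia markers were lower as a group (mean -0.06, adjusted p = 0.00396, and 0.396 with an estimated correlation). Gpr84, a receptor of medium-chain fatty acids induced on activated microglia, fell 1.35-fold (log2 fold change -0.43, SE 0.0652, adjusted p = 0.00516), Cx3cr1 was at -0.20 and Fcrls at 0.34, and adjusted over the list alone 3 members were lower and 1 higher.

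Reactive astrocyte genes were lower as a group in the Il1b KO (mean -0.08, adjusted p = 0.00123, and 0.595 with an estimated correlation), with Cp at -0.20, Nes at -0.19 and Vim at -0.10. NF-kB feedback and acute-phase targets were lower (mean -0.06, adjusted p = 0.0346, and 0.586 with an estimated correlation), with Saa2 at -0.33, Hp at -0.26 and Icam1 at -0.19. Skeletal muscle genes were lower in 14 of 14 members (mean -0.19, adjusted p = 4.52e-06, and 0.39 with an estimated correlation), with Atp2a1 at -0.49, Acta1 at -0.35 and Myh2 at -0.29. In these 3 lists 0 members passed either way. The muscle list mean varied more between wild-type arrays (SD 0.163) than between Il1b KO arrays (SD 0.0680), and its exact permutation p was 0.114. The reactive astrocyte call was lost without wild type replicate 3 (mean -0.05, adjusted p = 0.0743), and without Il1b KO replicate 1 the mean was -0.04 (adjusted p = 0.0426). The NF-kB call was lost without wild type replicate 3 (-0.06, adjusted p = 0.15), wild type replicate 4 (-0.05, adjusted p = 0.0584) or Il1b KO replicate 1 (-0.03, adjusted p = 0.217). Regulators of cell death did not pass as a group (mean -0.04, adjusted p = 0.0784), although Mlkl fell 1.29-fold (log2 fold change -0.37, SE 0.0524, adjusted p = 0.00328) and was the 1 member past the test over all genes and over the list alone, with Casp6 at -0.18 and Gadd45a at -0.14. Cytokines and chemokines did not pass as a group either (mean 0.12, adjusted p = 0.266). Beside Cxcl13, their members Cxcl2 and Ccl5 had log2 fold changes of 1.06 (SE 0.292, adjusted p = 0.14) and -0.29 (adjusted p = 0.0575), so 1 member passed over all genes, and adjusted over the list alone 2 were higher and 1 lower. With an estimated correlation 0 of the 11 calls held (2 lists at an unadjusted p under 0.05), and with fry 0 held (6 lists at an unadjusted p under 0.05).

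**Figure D3:**
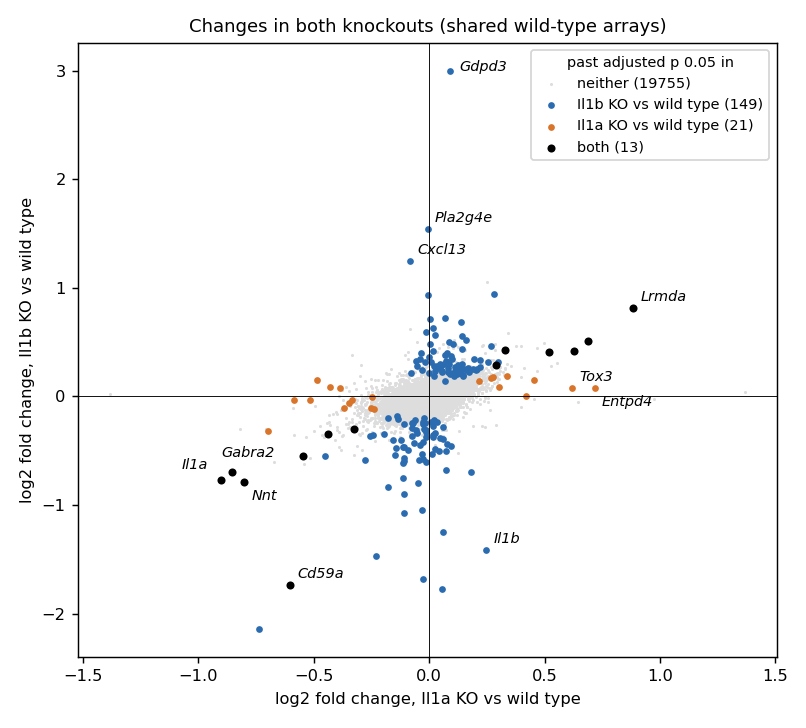
Log2 fold change of every gene in the Il1a KO (horizontal axis) and in the Il1b KO (vertical axis) against the same wild-type arrays, coloured by the comparison in which the gene passed an adjusted p of 0.05. The 13 genes that passed in both (black) lie on the same side of 0 in both knockouts, and Gdpd3, 8.01-fold higher in the Il1b KO, is the farthest from 0.

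The direct comparison of the Il1a KO with the Il1b KO tested where the knockouts differ from each other. Besides Il1b, which was 3.17-fold higher in the Il1a KO, the knockouts differed in Tox3, which was 1.45-fold higher in the Il1a KO (log2 difference 0.54, SE 0.0526, adjusted p = 1.46e-04), and in Gdpd3, which was 7.51-fold lower in the Il1a KO (log2 difference -2.91, SE 0.0976, adjusted p = 4.91e-09). Cxcl13 was 2.51-fold lower in the Il1a KO (log2 difference -1.33, SE 0.151, adjusted p = 5.34e-04) and Cd59a 2.19-fold higher (log2 difference 1.13, SE 0.0735, adjusted p = 2.25e-06). In all, 130 of 19938 genes passed, 69 higher and 61 lower in the Il1a KO, of which 29 differed by at least 1.5-fold. The arrays of the knockouts did not overlap in 7.24% of all genes, against the 2.86% that chance gives.

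Other genes higher in the Il1a KO than in the Il1b KO were Trim30d (3.54-fold), Trim12a (3.15-fold), G530011O06Rik (2.65-fold), Alox8 (2.48-fold), AA467197 (2.36-fold), Rpl34 (2.02-fold), Ly86 (1.95-fold), Etnppl, an enzyme of phospholipid breakdown found in astrocytes (1.84-fold), Arntl2 (1.72-fold) and Spint1 (1.68-fold). Other genes lower in the Il1a KO were Pla2g4e (2.92-fold), Masp2 (1.92-fold), Scgb3a1 (1.64-fold), Mrpl20 (1.63-fold), Il1bos (1.59-fold), Fam169a (1.57-fold), Znrd1as (1.55-fold), Rbm46 (1.53-fold), Depdc7 (1.53-fold) and Crnde (1.46-fold). The arrays of the 2 knockouts did not overlap in any of these genes, with adjusted p from 7.21e-08 to 0.0135. Without Il1a KO replicate 1 the count was 94 genes, and of 28 named genes 4 lost their call in at least 1 fit that left out an array (Bub1b, Gpr34, Gpr84 and Scgb3a1, with adjusted p up to 0.158 for Bub1b without Il1b KO replicate 3).

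Of the lists, cell cycle genes were higher in the Il1a KO than in the Il1b KO in 22 of 24 members (mean 0.13, adjusted p = 6.62e-09, and 0.482 with an estimated correlation). Bub1b, a checkpoint kinase of mitosis that lay in a stretch with other genes past the test on chromosome 2, was 1.57-fold higher (adjusted p = 0.0409) and was the 1 member past the test over all genes, against 2 adjusted over the list alone, and Ccna2 was at 0.30 and Aurkb at 0.20. Interferon-stimulated genes were higher (mean 0.18, adjusted p = 4.35e-05, and 0.68 with an estimated correlation), with Oasl2 at 0.49, Ifit2 at 0.26, Cmpk2 at 0.17 and 0 members past the test either way. Homeostatic microglia markers were higher by the test (adjusted p = 0.0233, and 0.612 with an estimated correlation) with a mean of 0.06 but a median of -0.0019, as 9 of 19 members lay above 0. Gpr84 was 1.29-fold higher (adjusted p = 0.0183) and Gpr34, a receptor of microglia, 1.24-fold higher (adjusted p = 0.0299), Siglech was at 0.30 (adjusted p = 0.259), and 4 members were higher adjusted over the list alone. The interferon mean was 0.28 without Il1a KO replicate 1 (adjusted p = 6.74e-11) and 0.07 without Il1a KO replicate 4 (adjusted p = 0.0466). The microglia call was lost without Il1a KO replicate 1 (mean 0.05, adjusted p = 0.143) or Il1b KO replicate 4 (0.05, adjusted p = 0.119).

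Monocyte and macrophage markers were lower in the Il1a KO than in the Il1b KO (17 of 25 members, mean -0.16, adjusted p = 8.74e-05, and 0.612 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, was at -0.55 (adjusted p = 0.0642), Clec4e at -0.70 (adjusted p = 0.161) and Fn1 at -0.25, and 0 members passed over all genes against 7 adjusted over the list alone. Immediate early and heat shock genes were lower (mean -0.09, adjusted p = 3.99e-04, and 0.482 with an estimated correlation), with Atf3 at -0.26, Egr1 at -0.22 and Ier3 at -0.24. Endoplasmic reticulum stress genes were lower (mean -0.05, adjusted p = 0.0131, and 0.482 with an estimated correlation), with Nupr1 at -0.28, Creld2 at -0.15 and Xbp1 at -0.11. Reactive astrocyte genes were lower (mean -0.06, adjusted p = 0.0131, and 0.79 with an estimated correlation), with Cd44 at -0.26, Stat3 at -0.11 and Gfap at -0.09. Each of these 3 lists had 0 members past the test over all genes and 1 adjusted over the list alone. Pericyte and fibroblast markers were lower (mean -0.09, adjusted p = 0.0131, and 0.612 with an estimated correlation), with Igf2 at -0.39, Slc6a13 at -0.30 and Col3a1 at -0.22. Of these, 0 passed over all genes and 2 adjusted over the list alone. Cytokines and chemokines were lower (mean -0.13, adjusted p = 0.026, and 0.612 with an estimated correlation), with Cxcl13 the 1 member past the test both ways, Ccl12 at 0.39 and Osm at -0.29. The reactive astrocyte call was lost without Il1a KO replicate 1 (mean -0.01, adjusted p = 0.334), Il1b KO replicate 3 (-0.03, adjusted p = 0.123) or Il1b KO replicate 4 (-0.03, adjusted p = 0.23), while without Il1b KO replicate 1 the mean was -0.10 (adjusted p = 1.69e-04). The cytokine call was lost without wild type replicate 3 (-0.13, adjusted p = 0.0523), Il1a KO replicate 1 (-0.10, adjusted p = 0.173), Il1b KO replicate 3 (-0.09, adjusted p = 0.144) or Il1b KO replicate 4 (-0.11, adjusted p = 0.119). The pericyte and fibroblast call was lost without Il1b KO replicate 4 (-0.08, adjusted p = 0.0934) and the endoplasmic reticulum stress call without Il1b KO replicate 3 (-0.04, adjusted p = 0.104), the array without which the monocyte and macrophage mean was -0.10 (adjusted p = 0.00997).

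Neutrophil markers did not pass the test between the knockouts (mean -0.05, median -0.06, adjusted p = 0.747), and neither did mature oligodendrocyte markers (mean 0.01, adjusted p = 0.497) or regulators of cell death (mean -0.01, adjusted p = 0.448). In these lists Itgam was at 0.34, Pglyrp1 at 0.15 and Trem1 at -0.49, Gjc3 at 0.15, Anln at 0.10 and Klk6 at -0.08, and Bmf at 0.21, Mlkl at 0.11 and Gadd45g at -0.21, with 0 members past the test either way. With an estimated correlation 0 of the 9 calls held (1 list at an unadjusted p under 0.05), and with fry 0 held (3 lists at an unadjusted p under 0.05). Without Il1b KO replicate 4 the number of lists was 5.

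The genes shared by both knockouts were counted by direction. Of the 34 and 162 genes, 13 passed in both comparisons, 6 higher (Lrmda, Ankub1, Aim2, Pkd2l1, Olfml1 and Scn4b) and 7 lower (Il1a, Gabra2, Nnt, Cd59a, Ccl28, Acat3 and Ermard), and 0 moved in opposite directions. The 13 were 6 without Il1b KO replicate 1, 7 without wild type replicate 4, Il1a KO replicate 1 or Il1b KO replicate 3, and 8 without Il1a KO replicate 3 or 4. Lists of these sizes drawn independently would share 0.138 genes in the same direction. When the wild-type arrays were split between the comparisons, the overlap was 4 to 8 genes, with a mean of 6, and Gabra2, Il1a, Lrmda and Nnt passed in both knockouts in all 6 splits. Nnt was at -0.80 in the Il1a KO and -0.79 in the Il1b KO, Gabra2 at -0.86 and -0.69, and Lrmda at 0.88 and 0.81, and the difference between the knockouts passed in 0 of these 3 by limma (adjusted p = 0.964, 0.484 and 0.812). Cd59a fell in both but further in the Il1b KO (difference adjusted p = 2.25e-06). Across genes the log2 fold changes of the knockouts correlated with r = 0.504, against 0.498 in simulated unchanged groups with the same wild-type arrays, and their covariance was 0.00437 against 0.00271, a difference of 0.00166. Genes are not independent replicates. With the wild-type arrays split, r lay between -0.218 and 0.262.

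Because Il1a and Il1b are neighbours on chromosome 2, genes around them were compared with the rest. The order of genes was taken from the GRCm38.p6 annotation. Of the 201 measured genes made up of Il1a and 100 neighbours on each side, 13 passed in the Il1b KO, against 148 of 19655 elsewhere (Fisher's exact test, two-sided, p = 1.02e-08, adjusted p = 3.06e-08). They were Il1a, Il1b, Il1bos and AA467197, and 9 genes named after their values were seen. Of these 9, Adal, Bloc1s6, Catsper2 and Slc27a2 were higher. B2m, the light chain of MHC class I, Kcnip3, Lcmt2, Mall and Sqor were lower. Without Il1a and Il1b the count was 11 (Fisher's exact p = 6.18e-07). In the Il1a KO the window held 2 such genes, Il1a and Trmt6 (Fisher's exact p = 0.0463), and 1 without the targeted genes (exact p = 0.283). With 50 or 200 neighbours on each side the exact p in the Il1a KO was 0.159 and 0.15. Between the knockouts 10 genes of the window differed (Fisher's exact p = 7.81e-07). Fisher's test treats genes as independent. Outside this window, 70 of 148 called genes of the Il1b KO had another within 10 measured neighbours, against a mean of 20.3 in random sets. The Fisher p may therefore overstate how far this window stands apart.

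**Figure D4:**
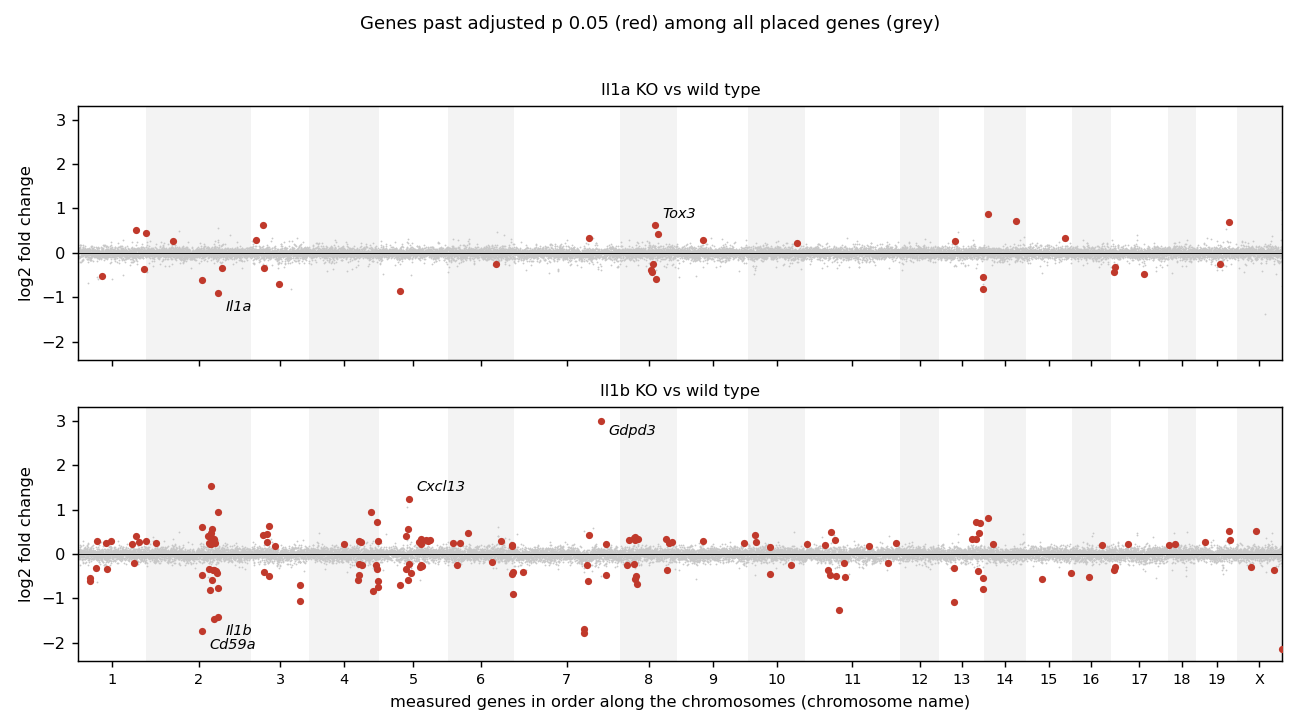
Log2 fold change of each placed gene (vertical axis) against its order along the chromosomes (horizontal axis, shaded by chromosome) for the Il1a KO and the Il1b KO against wild type, with genes past an adjusted p of 0.05 in red. In the Il1b KO such genes were 26 of 1732 measured genes on chromosome 2, the chromosome of Il1a and Il1b. They were 17 of 1140 on chromosome 5 and 14 of 955 on chromosome 8, near-equal shares, so chromosome 2 as a whole did not stand out. In the Il1a KO they were 6 of 955 on chromosome 8, the chromosome of Tox3.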

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

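The tests of clusters of neighbouring genes as strain segments, of the Tox3 neighbourhood as a strain segment, of splits of the wild-type arrays, of the wild-type substrain and of the oligodendrocyte lists were chosen only after the result was seen. Other splits of the 8 arrays compared did not give as many genes for any of the 3 counts. This test cannot exclude chance, because the real split can at best rank first of 35. The other splits also put arrays of both groups on each side, so group differences add to their spread and lower their counts. For the Il1a KO 1 of 35 splits, the real one, gave 34 genes and the highest other gave 0. For the Il1b KO 1 of 35 gave 162 and the highest other gave 34. Between the knockouts 1 of 35 gave 130 and the highest other gave 0.

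Called genes lay next to one another on the chromosomes in the Il1b KO, where 81 of 161 placed genes had another within 10 measured neighbours against a mean of 23.9 in random sets (permutation p = 1e-05, the smallest the draws can give). Chromosome segments of another strain carried by the knockout line are a candidate explanation, and Cd59a with Cd59b and Depdc7, Pla2g4e with Tyro3, Zfp106 and Snap23, Trim12a with Trim30d, and Cxcl13 with Cxcl11, Naaa and Shroom3 were such groups. Related genes that share probes do not account for the whole count, since 65 of 144 genes clustered with 1 gene kept per symbol stem. That test drops pairs of 1 stem such as Trim12a with Trim30d, so for this pair shared probes or family stay open. Neighbouring genes that vary together did not give this count in any other split, where the highest was 39. Those splits mix both groups, which adds group differences to the spread, so they cannot exclude this explanation. In the Il1a KO 6 of 34 genes clustered (permutation p = 0.0149, and 6 with 1 gene per stem), but another split reached 7, so neighbours that vary together stay open there as well. For Tox3, 5 other called genes lay within 100 measured neighbours (Fisher's exact p = 1.86e-05, from a test that treats genes as independent). The other splits, which mix both groups, held at most 1. A strain segment is a candidate explanation there, but an effect of the missing interleukin-1 alpha on Tox3 itself stays open, because line and genotype coincide.

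Wild type stood apart from both knockouts in 13 genes, among them Nnt, Gabra2 and Lrmda, and in 6 to 13 when single arrays were left out (6 without Il1b KO replicate 1, and the others are given above). Noise that differs between the wild-type arrays is unlikely alone to account for Gabra2, Il1a, Lrmda and Nnt. These 4 genes were called in both knockouts in all 6 splits of those arrays between the comparisons. The 6 splits reuse the same 4 wild-type arrays. A shift common to all 4 would enter every split, so the splits cannot exclude it. Il1a is the targeted gene of the Il1a KO, so its call there was given by the design. For the other genes shared controls and chance stay open, with Ccl28 called in both in 5 of 6 splits, Cd59a in 4, Ankub1 and Olfml1 in 1 and Acat3, Aim2, Ermard, Pkd2l1 and Scn4b in 0, as splitting leaves fewer arrays to each fit, and the simulations of unchanged groups, in which at most 0 calls were shared, made a mean of 0.04 and 0.01 calls per comparison and so decide nothing. Ccl28 lay with Nnt in a stretch of 6 measured genes on chromosome 13, and its log2 fold change was -0.55 in each knockout. Its calls may therefore not be separate from those of Nnt. Wild-type mice of another C57BL/6 substrain than the knockouts are a candidate explanation, as Nnt and Gabra2 are known to be low in C57BL/6J, and all 4 of their calls in the knockouts were lower. Substrain and genotype, with a response to the loss of either cytokine, cannot be told apart here, because the labels give no substrain and any such difference would coincide with the group.

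Oligodendrocyte lists were higher in both knockouts, and members that vary together between arrays may account for the small p of the preset correlation, since the lower of the adjusted p with an estimated correlation was 0.261. For mature oligodendrocyte markers the unadjusted camera p with that correlation was 0.0123 in the Il1a KO and 0.0396 in the Il1b KO. With fry their adjusted p was 0.0558 and 0.0596, above the threshold. A lower share of infiltrating cells would raise markers of all resident types alike, and neuron and precursor lists were higher and the neutrophil list lower in both knockouts, with the astrocyte list higher and the monocyte list lower in the Il1a KO, although of these calls only those of precursors, and of neurons in the Il1b KO, held without each single array. With an estimated correlation 0 of these calls held (lowest camera adjusted p = 0.261 in the Il1a KO and 0.39 in the Il1b KO). On the other side, means were -0.02 in both knockouts for motor neurons (adjusted p = 0.498 and 0.554), 0.0081 and 0.04 for endothelial markers (0.861 and 0.482), and -0.0060 and -0.06 for resident microglia (0.466, and 0.00396 with 0.396 at an estimated correlation), and monocyte and macrophage markers had a mean of 0.08 in the Il1b KO (adjusted p = 0.137). Mature oligodendrocyte markers shifted further than neuron, astrocyte and microglia markers in both knockouts (exact permutation p = 0.0286 in each, the smallest 4 against 4 can give), and by 0.15 and 0.14 more than motor neuron markers, a difference that varied more between arrays (exact permutation p = 0.0571 and 0.143), but their shift was not told apart from that of precursors in either knockout, or of endothelial cells in the Il1b KO (exact permutation p up to 1). A lower share of infiltrating cells therefore stays open. Less carried-over muscle and less loss of oligodendrocytes stay open as well, and neither was tested. Muscle genes were lower in 14 of 14 members in both knockouts, but their list mean varied between wild-type arrays (SD 0.163, exact permutation p = 0.143 and 0.114).

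Single arrays lay far from the other 3 of their group in 22 of 432 groups tested (5.09%), and chance gives about 1 in 20. Il1a KO replicate 1 had 6 of these, with Xist at 6.47, Eif2s3y at 9.15, Kdm5d at 7.85, Uty at 8.42, Olig1 at 10.7 and Itgam at 9.50. In wild type they were Entpd4 (10.7) and Tox3 (8.02) in replicate 4, Il1a (6.22), Stard4 (8.76) and S100a10 (12.1) in replicate 1, Ccl6 (10.7) and Gad1 (10.5) in replicate 2 and Cmpk2 (8.85) in replicate 3. In the Il1b KO they were Timp1 (11.6) and Fam169a (9.21) in replicate 1, Aurkb (7.54) in replicate 2, Entpd4 (10.8) and Arntl2 (7.63) in replicate 3 and Ccna2 (7.12) in replicate 4. In Il1a KO replicate 2 they were Ly86 (10.9) and Pglyrp1 (9.89).

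Of the 9 lists in which the knockouts differed from each other by camera at the preset correlation, 6 had opposite signs of the test against wild type, and interferon-stimulated genes, reactive astrocyte genes and homeostatic microglia markers did not. Since 0 of the 6 passed against wild type in both knockouts, and immediate early genes, pericyte markers and cytokines in neither, these signs do not show opposite responses. Between the knockouts the 6 were cell cycle genes (adjusted p = 6.62e-09), monocyte and macrophage markers (8.74e-05), immediate early and heat shock genes (3.99e-04), endoplasmic reticulum stress genes (0.0131), pericyte and fibroblast markers (0.0131) and cytokines and chemokines (0.026), and with an estimated correlation the lowest adjusted p was 0.482. The last 2 of these calls and that of endoplasmic reticulum stress genes were lost without single arrays named above. Probe sets without a listed gene, outside the comparisons above, held 9 calls in the Il1a KO, 33 in the Il1b KO and 20 between the knockouts among 12147, or 0.0741%, 0.272% and 0.165%, below the 0.243%, 0.683% and 0.5% of the listed ones.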

How the results depend on the processing

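Fits without called genes that lie near another, and fits without wild type replicates 1 and 3, were chosen only after seeing the data. The number of arrays limits all counts, and the dim signal of Il1a, near the array background, limits its fold. For the Il1a KO the count of 34 genes was 15 with only the 2 groups in the fit, 74 with a trend and robust moderation, 306 with array weights, 68 among genes at or above the median level, 10 with a fold of at least 1.5 and 66 with all probe sets on their own. For the Il1b KO the count of 162 was 85 with only the 2 groups, 309 with trend and robust moderation, 1145 with array weights, 303 among genes at or above the median level, 32 with a fold of at least 1.5, 300 at an adjusted p of 0.1 and 81 without called genes near another. Between the knockouts the count of 130 was 244 with array weights, 29 with a fold of at least 1.5 and 48 without called genes near another. Fewer genes tested, a second threshold or a looser one change a count by construction, and otherwise the cause was not tested. Apart from the omissions of single arrays given below, the other alternatives for these counts stayed within 1.5 times, among them 24, 128 and 158 genes without wild type replicates 1 and 3 (10, 9 and 8 lists). Which direction held more genes also depended on the processing. In the Il1b KO the 84 higher and 78 lower genes were 68 and 84 when quantile-normalized again, 104 and 76 with arrays centred on their medians, 230 and 73 at or above the median level, 32 and 53 with only the 2 groups and 50 and 70 with the replicate block. In the Il1a KO the 15 and 19 were 42 and 32 with trend and robust moderation and 39 and 29 at or above the median level, and between the knockouts the 69 and 61 were 53 and 67 at or above the median level. With array weights they were 191 and 115 in the Il1a KO, 749 and 396 in the Il1b KO and 121 and 123 between the knockouts. With all probe sets on their own they were 40 and 26 in the Il1a KO and 90 and 103 in the Il1b KO. Trend and robust moderation gave 205 and 104 in the Il1b KO and 75 and 78 between the knockouts.

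List calls went from 13, 11 and 9 to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry, and between the knockouts to 3 among genes at or above the median level. The 13 shared genes were 5, 4, 6, 8, 6 and 7 with the wild-type arrays split, where each fit had fewer arrays. Near Il1a, windows of 50 and 200 neighbours and an unadjusted p of 0.01 gave 1, 2 and 12 genes in the Il1a KO (exact p = 0.159, 0.15 and 0.012), 6, 22 and 25 in the Il1b KO and 4, 23 and 16 between the knockouts. The cytokine list in the Il1b KO turned to lower among genes at or above the median level (adjusted p = 0.0535).

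Leaving out each array in turn gave 18 to 49 genes for the Il1a KO, 106 to 177 for the Il1b KO and 88 to 146 between the knockouts. They were over 1.5 times fewer without wild type replicate 4 (18), Il1a KO replicate 3 (19) or Il1a KO replicate 4 (19) for the Il1a KO, and without wild type replicate 4 (106) or Il1b KO replicate 1 (107) for the Il1b KO. The omissions gave 7 to 14, 10 to 13 and 5 to 10 lists. The shared genes were 6 to 13, and fewest without Il1b KO replicate 1. They were 7 without wild type replicate 4, Il1a KO replicate 1 or Il1b KO replicate 3, and 8 without Il1a KO replicate 3 or 4. Il1a stayed at -0.94 to -0.78 in the Il1a KO and at -0.84 to -0.66 in the Il1b KO, Il1b at -1.49 to -1.34 in the Il1b KO and at 0.20 to 0.32 in the Il1a KO, each on the same side of the threshold. Il1rn in the Il1a KO ranged from -0.0032 without wild type replicate 2 to 0.15. Between the knockouts the mature oligodendrocyte list turned direction without Il1a KO replicate 1 (adjusted p = 0.56) or Il1b KO replicate 2 (0.584), within a range of 0.134 to 0.777 over the omissions, and the neutrophil list without Il1a KO replicate 2 (0.766), Il1a KO replicate 3 (0.776) or Il1b KO replicate 1 (0.0511), and neither passed in any of these. The cause was not tested. Calls that some omission ended numbered 8 of 23 named genes and 7 of 13 lists in the Il1a KO, 1 of 27 and 4 of 11 in the Il1b KO, and 4 of 28 and 5 of 9 between the knockouts.

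With the replicate number as a replicate block the counts were 26, 120 and 105 genes and 13, 11 and 10 lists. Arrays of the same number correlated with r from -0.374 to 0.441 across genes after removal of group means, with 2 of 12 pairs above 0.1, so the numbers were not taken to pair the arrays. Over all alternatives, the named genes gave 4101 values with the same direction and side of the threshold, 112 that fell below it, 100 that passed it and 1 that reversed, and the lists gave 602, 125, 4 and 6.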

Other observations

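In the Il1b KO 3 members of the vessel lists passed the test over all genes, though the lists did not. Rgs5 (log2 fold change 0.22, adjusted p = 0.033) and Abcc9 (0.20, adjusted p = 0.0187), both of pericytes, rose, as did Vwf, the clotting factor carrier of endothelium (0.30, adjusted p = 0.0405). Abcc9 lay in a stretch of 26 measured genes on chromosome 6 with 4 other genes past the test (Bcat1, Etfrf1, Med21 and Arntl2). The pericyte and fibroblast list had a mean of 0.07 (adjusted p = 0.0661) and the endothelial list of 0.04 (adjusted p = 0.482). Sox9, a transcription factor of astrocytes, fell in the Il1b KO (-0.19, adjusted p = 0.0405), while the astrocyte list had a mean of 0.04 (adjusted p = 0.15). Rgs5, Abcc9, Vwf, Sox9 and the neighbours of Abcc9 other than Arntl2 were named after their values were seen.

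Other lists that did not pass in the Il1a KO were cell cycle genes (mean 0.02, adjusted p = 0.568), Schwann cell and dorsal root markers (0.03, adjusted p = 0.568), motor neuron markers (-0.02, adjusted p = 0.498), homeostatic microglia (-0.0060, adjusted p = 0.466), endothelial markers (0.0081, adjusted p = 0.861) and pericyte and fibroblast markers (-0.01, adjusted p = 0.775). Lymphocyte markers (mean -0.03, adjusted p = 0.587) and interferon-stimulated genes (mean -0.0018, adjusted p = 0.808) had medians of the opposite sign. In the Il1b KO, monocyte and macrophage markers had a mean of 0.08 (adjusted p = 0.137), immediate early genes of 0.04 (adjusted p = 0.158), lymphocyte markers of -0.04 (adjusted p = 0.186), and endoplasmic reticulum stress genes of 0.02 (adjusted p = 0.564). Motor neuron markers (mean -0.02, adjusted p = 0.554), Schwann cell markers (0.02, adjusted p = 0.719) and the interleukin-1 family (0.0040, adjusted p = 0.919) differed in sign between mean, median or test. Between the knockouts the interleukin-1 family had a mean of -0.09 (adjusted p = 0.0772), and the neutrophil list's test leaned higher although its mean and median were negative. The 10 other lists without a call or a value above for this comparison had adjusted p from 0.431 to 0.96.

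Of the lists summarised without a set test, the 4 erythroid genes had a mean log2 fold change of -0.12 in the Il1a KO and -0.09 in the Il1b KO (exact permutation p = 0.0857 and 0.171). The 21 ribosomal protein genes had -0.01 and -0.0014 (exact permutation p = 0.6 and 0.943), and the 1 measured mitochondrially encoded gene, COX2, had -0.05 and -0.06. The 4 sex-linked genes had a mean of 0.40 in the Il1a KO (exact permutation p = 0.543), from replicate 1 alone, and -0.0033 in the Il1b KO (exact permutation p = 0.943).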
